A study of Mus musculus with 16 samples.

How the data were processed

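RNA was measured on 16 one-colour Affymetrix arrays, each hybridised with biotin-labelled total RNA from brain tissue of mice aged 2.5 months on a mixed C57BL/6 and CD1 background. The tissues were the subependymal zone (SEZ), the niche beside the lateral ventricle where adult neural stem cells give rise to new neurons, and the core of the olfactory bulb (OB), where those neurons arrive. Conditional knockout samples (cKO) carried 2 floxed copies of Brg1, and controls carried 1 floxed copy. Brg1, whose gene is Smarca4, is an ATPase of the SWI/SNF chromatin remodelling complex. All animals carried the tamoxifen-dependent recombinase CreERT2 under the Glast locus, whose gene is Slc1a3. The labels list no treatment, and when recombination was induced is not given in the sources used here. One exception in the labels is SEZ control replicate 5, whose genotype is given without a floxed copy. The groups held 3 cKO and 5 control samples in each tissue, and the labels call them biological replicates.

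The deposited values are log2 expression values per probe set, and per the submitters' processing notes they were made with RMA (background correction, quantile normalisation and summarisation of probes) in Affymetrix Expression Console 1.2. The genome build behind the probe sets was not given in the sources used here, so no coordinates are printed. RNA was extracted with a column kit that included DNase treatment, per the labels' protocols. Array medians lay between 7.45 and 7.65, and single values between 3.51 and 14.8. No 2 arrays were duplicates, the highest correlation between any 2 being 0.9975. For arrays, the number of samples limits the precision.

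Of 35556 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 had none. Symbols were looked up through Entrez identifiers in a RefSeq gene table of the assembly GRCm38.p6, which held 21698 of them, and 0 symbols changed. Probe sets with no symbol or several symbols were left out of the main tests. Where a gene had more than 1 probe set, which held for 999 genes, the brightest was used. This gave 19938 genes.

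All 16 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 4 groups of tissue by genotype and no covariate, leaving 12 residual degrees of freedom per gene and 4.34 prior degrees of freedom. The contrasts were cKO minus control in each tissue, the difference between these effects (SEZ effect minus OB effect), and OB minus SEZ in controls. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 29 lists with at least 3 measured members. They covered cell types of both tissues and their surroundings, chromatin complexes, signalling pathways and housekeeping functions. The same lists were run with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way. List means were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 5 samples was 0.0179. The list of the neurogenic network (Pax6, Sox11, Nfib and Pou3f4) was reported by this study on these samples, so it is not independent evidence of its own direction.

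Groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The values of single lists under the alternatives were first computed for part of the lists, and after that run they were extended to all 29 and to OB against SEZ. The rule named Smarca4, up to 10 genes with the largest change each way among those that passed in a tissue, filled to 5 per direction by the smallest unadjusted p, up to 4 members of each list described, and a set of fate genes (Pax6, Sox11, Nfib, Pou3f4, Sox4, Dlx1, Dlx2, Dcx, Egfr, Olig2, Sox10, Pdgfra and Gfap, and another that is not reported here). For the difference between tissue effects and for OB against SEZ it named up to 5 per direction, filled to 3. A subset of the genes under this rule is named here.

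The model was tested on simulated data for 19938 genes with the group sizes of this design. For SEZ cKO against control it called 65 of 100 genes seeded with a log2 change of 0.5 and 98 of 100 seeded with 1, with 6 false calls. For OB it called 69 and 97 of 100, with 10 false calls. The simulated noise was drawn independently for each gene and array, without the clusters of arrays described below. Changes of both sizes and a shift of the cell cycle list were seeded together, which eases the adjusted threshold. The shares called may therefore not hold for the real arrays.

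Alternatives tried were fits on the arrays of 1 tissue, only genes above the median level, cyclic loess, centring on medians, array weights, a robust intensity trend, the replicate number as a block, other handling of several probe sets, an adjusted p under 0.1, covariates for sex-linked genes and for neighbouring tissue, and leaving out each array in turn. Chosen after seeing the data were the strongest within-group component as a covariate and the 2 clusters of arrays on it as a block. Both are made from the residuals and so make their tests optimistic. Fits without both cKO replicate 1 arrays or both cKO replicate 3 arrays were also chosen then. So was a fit without SEZ control replicates 2 and 4, which had high levels of cortical genes. An alternative value counted as reversed where its sign changed and it passed the threshold with either setting. Sign changes of values that passed with neither are included among the values that stayed or moved, and were also counted separately.

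Replicate numbers were checked as pairs. Deviations from the group means correlated between same-numbered OB cKO and OB control samples with r of 0.491, 0.397 and 0.306 over genes. Those of OB and SEZ controls did so as well, with r from 0.117 to 0.556. These numbers were treated as possible pairs. Every pair with a positive r lay within a single array cluster, which alone could give such r. OB cKO 2 and OB controls 1, 4 and 5 correlated best with another number, so pairing was not established. The labels also give the SEZ and OB samples of control 5 different genotypes. Same-numbered SEZ cKO and SEZ control samples had r of -0.442, 0.162 and 0.601 and were not taken as paired. Figures were drawn with matplotlib 3.10.9.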

Results

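Expression was compared between Brg1 conditional knockout (cKO) and control mice in the subependymal zone (SEZ) and in the core of the olfactory bulb (OB). Each tissue had 3 cKO and 5 control arrays, and values are log2 expression, given as mean ± SD. The question was which genes depend on the chromatin remodeller Brg1 in the birthplace and in the destination of adult-born neurons.

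Smarca4, the gene of Brg1, was measured at 10.71 ± 0.08 (n = 3) in SEZ cKO and 10.71 ± 0.04 (n = 5) in SEZ control samples. In OB its level was 11.02 ± 0.06 in cKO and 11.02 ± 0.04 in control samples. The 95% interval of the difference ran from -0.13 to 0.12 in SEZ and from -0.12 to 0.13 in OB. The probe set was not resolved by exon and the tissue mixes recombined with other cells, so this level checks nothing about the deleted part of the gene.

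Sex-linked genes matched between the SEZ and OB samples of the same number in 7 pairs. In the cKO replicate 1 pair they did not, with Xist, the RNA of the inactive X chromosome, at 12.4 in the SEZ sample and 6.08 in the OB sample. The mean of the Y-linked genes was 5.31 in that SEZ sample and 9.51 in that OB sample. Slc1a3, the glutamate transporter of astrocytes whose locus drives the recombinase, was 8.16 in SEZ cKO replicate 3 against 11.16 to 11.79 in the other SEZ samples. In OB cKO replicate 3 it was 8.85 against 11.64 to 12.27.

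**Figure D1:**
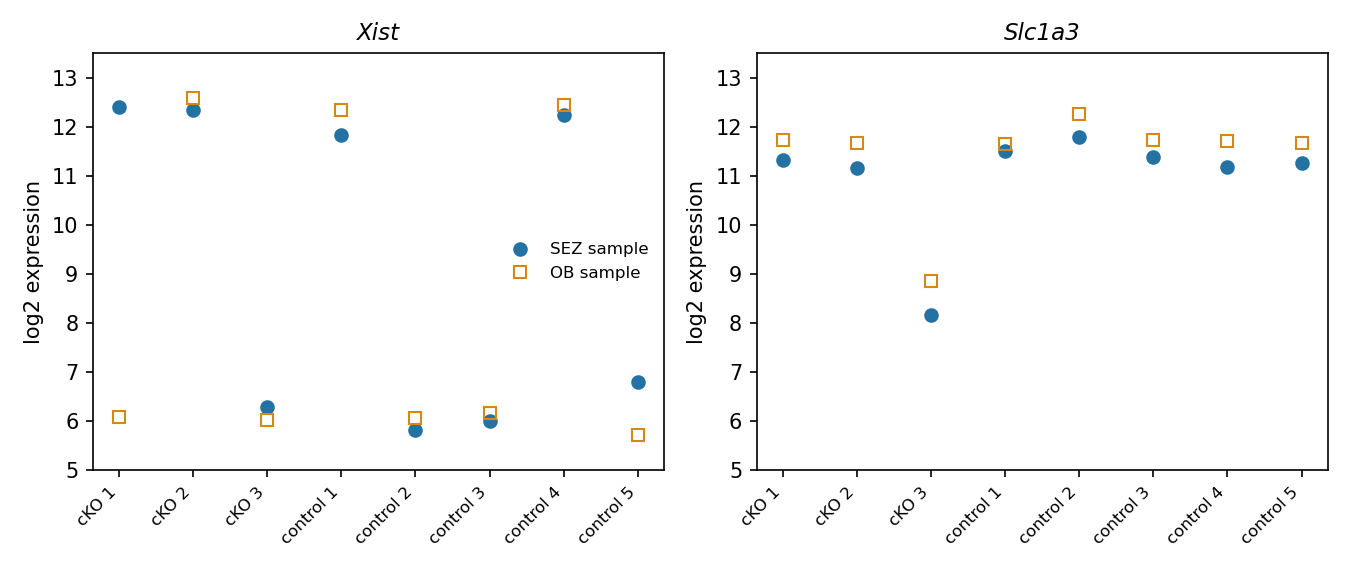
Log2 expression of Xist (left) and Slc1a3 (right) in each of the 16 samples by genotype and replicate number, with filled circles for SEZ and open squares for OB. The OB minus SEZ difference of Xist is -6.32 in the cKO 1 pair, and Slc1a3 lies at 8.16 and 8.85 in the cKO 3 pair, below all other samples.

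In OB, 9 genes fell in cKO samples and 0 rose. Prokr2, the receptor of prokineticin 2, a guidance cue of neuroblasts entering the bulb, fell from 11.28 ± 0.22 (n = 5) to 9.35 ± 0.34 (n = 3), a log2 change of -1.92 (SE 0.21, adjusted p = 0.000629). Cd24a, a surface glycoprotein of migrating neuroblasts, changed by -1.50 (SE 0.20, adjusted p = 0.00525). Islr2, a membrane protein of axon outgrowth, changed by -1.29 (SE 0.11, adjusted p = 3.53e-05). The other 6 were the secreted Wnt modulator Sfrp2 (-1.13), the polysialyltransferase St8sia2 (-0.84), the G protein subunit Gng2 (-0.76), Nrep (-0.71), the tubulin Tubb2b (-0.58) and the polycomb methyltransferase Ezh2 (-0.47), with adjusted p from 0.00525 to 0.0394.

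In all 9 genes, each of the 3 cKO samples lay below each of the 5 controls. The genes were chosen by the test on these same samples, so this is not further support. At an unadjusted p under 0.05, limma counted 700 genes where 997 are expected by chance. With the replicate number as a block 5 genes passed, and Sfrp2, Nrep, Tubb2b and Ezh2 did not. The count was 2 (Islr2 and Prokr2) without OB cKO replicate 3, and 5 without OB control replicate 4 or without OB control replicate 5. It was 28 with the strongest within-group component as a covariate and 3 from the OB arrays alone.

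The neuroblast list, genes of migrating neuroblasts and young interneurons, fell in OB cKO samples. Of its 25 measured members 4 fell (Cd24a, St8sia2, Nrep and Tubb2b) and 21 had estimates below 0, against 10 that fell when adjusted over the list alone. The mean over the list was 10.54 ± 0.11 in cKO and 10.86 ± 0.07 in control samples, a difference of -0.32 (95% interval -0.43 to -0.21, camera adjusted p = 1.2e-15). The call held with an estimated correlation (adjusted p = 0.00489) and with fry (adjusted p = 0.00148). Among members that did not pass singly, Sox4 was at -0.49 (SE 0.12, adjusted p = 0.433), Dcx at -0.32 (SE 0.09), Dlx2 at -0.20 and Dlx1 at -0.08, each of the last 3 with an adjusted p of 1.

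The 4 transcription factors of the neurogenic network named by the study had a mean difference of -0.40 in OB (95% interval -0.54 to -0.25, camera adjusted p = 1.59e-05, adjusted p = 0.00489 with an estimated correlation). None passed singly over all genes. Sox11 was at -0.89 (SE 0.19, adjusted p = 0.291), Pou3f4 at -0.38 (SE 0.12), Nfib at -0.31 (SE 0.08) and Pax6 at -0.02 (SE 0.12). Adjusted over the list alone, Sox11, Nfib and Pou3f4 fell, which is not independent evidence because the study chose the list on these samples.

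The microglia and macrophage list was called lower in OB by camera (adjusted p = 0.00249) but not with an estimated correlation (adjusted p = 0.54). Its mean difference was -0.13 (95% interval -0.26 to 0.01), and 18 of 23 members had estimates below 0. Trem2, a microglial lipid receptor, was at -0.22 (SE 0.08) and the lysosomal protease gene Ctss at -0.41 (SE 0.19), both with an adjusted p of 1. Other glial lists did not pass. The myelinating oligodendrocyte list differed by -0.05 (95% interval -0.35 to 0.25), the oligodendrocyte progenitor list by -0.04 (-0.20 to 0.13), and the astrocyte and neural stem cell list by -0.09 (-0.27 to 0.10). Its member Slc1a3, low in cKO replicate 3, was at -1.05, and the other 27 members differed by -0.05 (-0.21 to 0.10). The synaptic maturation list differed by 0.03 (-0.05 to 0.11) and was not called (camera adjusted p = 0.245), although the fit with the replicate number as a block called it higher, with 4 lists called in all where 3 were called without the block. It was also called higher among genes above the median level, with cyclic loess, and without OB cKO replicate 3 or OB control replicate 5.

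The exact permutation test of a list's mean gave p = 0.0179 for the neuroblast list and for the neurogenic network list in OB, the smallest this design allows, so no list passed it after adjustment. After each group's mean was removed, arrays were cut into 2 clusters by the sign of the strongest remaining component. By this construction the genotype cannot explain the clusters. For the neuroblast list in OB the cKO minus control difference was -0.26 in one cluster (1 cKO, 3 control) and -0.33 in the other (2 cKO, 2 control).

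**Figure D2:**
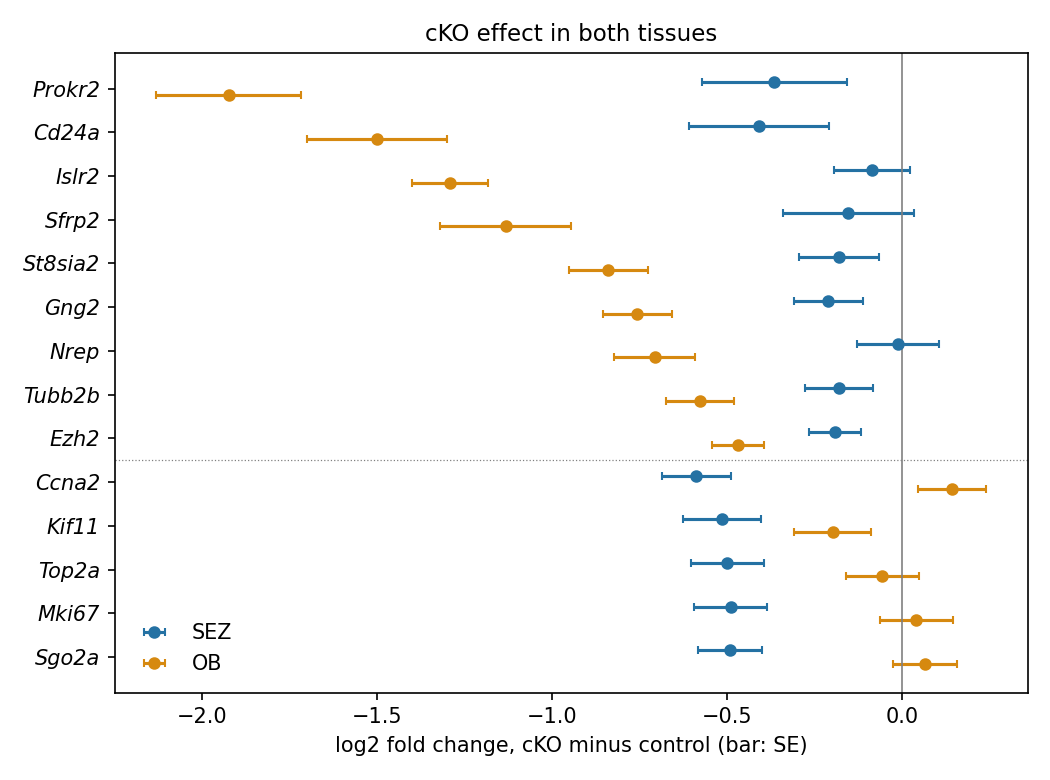
Log2 fold change, cKO minus control, in SEZ (blue) and OB (orange) for the 9 genes that passed in OB (above the dotted line) and for 5 cell cycle genes with low p in SEZ (below it), with bars of 1 SE. Prokr2 reached -1.92 in OB, and Ccna2 lay at -0.59 in SEZ, where it did not pass in the fit plotted. Ccna2 passed with the array cluster as a block, which is made from the residuals and so is optimistic.

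In SEZ, no gene passed in limma, and 492 genes had an unadjusted p under 0.05 where 997 are expected by chance. With the array cluster as a block, a choice made after seeing the data, 2 genes passed and both were lower in cKO. They were Ccna2 and the proliferation marker Mki67, each with an adjusted p of 0.00554. The clusters were cut from the residuals of the same arrays, which makes this adjusted p optimistic. With the within-group component as a covariate 4 passed, Ccna2, Mki67, Kif11 and Nusap1. Ccna2, cyclin A2, had the lowest p, at -0.59 (SE 0.10, adjusted p = 0.268), with 8.05 ± 0.14 (n = 3) in cKO and 8.64 ± 0.14 (n = 5) in control samples. The sterol carrier Scp2 was at -0.57 (SE 0.10, adjusted p = 0.268), the cohesin protector Sgo2a at -0.49 (SE 0.09, adjusted p = 0.395), the mitotic motor Kif11 at -0.51 (SE 0.11), the topoisomerase Top2a at -0.50 (SE 0.10) and Mki67 at -0.49 (SE 0.10), each of the last 3 with an adjusted p of 0.758.

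The transit-amplifying and cell cycle list, genes of dividing progenitors, fell in SEZ cKO samples. All 28 measured members had estimates below 0, and 0 passed singly over all genes, against 13 that fell when adjusted over the list alone. The mean over the list was 7.40 ± 0.04 in cKO and 7.63 ± 0.03 in control samples, a difference of -0.24 (95% interval -0.32 to -0.16, camera adjusted p = 1.99e-30). The call held with an estimated correlation (adjusted p = 0.000136) and with fry (adjusted p = 0.000346). Within the 2 array clusters the differences were -0.21 (2 cKO, 3 control) and -0.29 (1 cKO, 2 control). The exact permutation p was 0.0179, the smallest possible, and 0.173 after adjustment.

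The neuroblast list was called lower in SEZ by camera (adjusted p = 7.54e-07) but not with an estimated correlation (adjusted p = 0.0894). Its mean difference was -0.14 (95% interval -0.25 to -0.03), with 20 of 25 estimates below 0. Adjusted over the list alone Dlx1 (-0.56, SE 0.14) and Dcx (-0.33, SE 0.09) fell. Over all genes their adjusted p was 1. Dlx2 was at -0.42 (SE 0.15) and did not pass.

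The neurogenic network list was not called in SEZ. Its mean difference was -0.12 (95% interval -0.27 to 0.02, camera adjusted p = 0.0538, adjusted p = 0.234 with an estimated correlation), and its exact permutation p was 0.0179, or 0.173 after adjustment. All 4 members had estimates below 0, Pax6 at -0.12 (SE 0.12), Sox11 at -0.13 (SE 0.19), Nfib at -0.15 (SE 0.08) and Pou3f4 at -0.10 (SE 0.12), none passing. The list was called lower in 7 of 27 alternatives, among them those without SEZ cKO replicate 3 (adjusted p = 0.0267) and without SEZ control replicate 1 (adjusted p = 0.0443), with adjusted p over all of them from 0.00249 to 0.421.

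The interferon response list was also called lower in SEZ (camera adjusted p = 0.00528), but not with an estimated correlation (adjusted p = 0.904). Its mean difference of -0.16 had a 95% interval from -0.61 to 0.30. The list's median, -0.16 over all arrays, was 0.02 without SEZ cKO replicate 1, and the call was lost without SEZ control replicate 4 or without SEZ control replicate 5. Its members Rsad2 and Gbp3 were at -0.29 and -0.26.

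Lists of other lineages did not pass in SEZ. The oligodendrocyte progenitor list differed by 0.02 (95% interval -0.15 to 0.19), with Olig2 at 0.07, Sox10 at -0.01 and Pdgfra at 0.11. The myelinating oligodendrocyte list differed by -0.02 (-0.32 to 0.28), the ependymal list by 0.04 (-0.13 to 0.22) and the astrocyte and neural stem cell list by -0.04 (-0.23 to 0.14). Leaving out 1 array gave calls to some of these. The myelinating oligodendrocyte list was called lower without SEZ cKO replicate 1 (median -0.09, adjusted p = 0.0321) and without SEZ control replicate 3 (median -0.10, adjusted p = 0.011). The ependymal list was called higher without either of these, with medians of 0.10 and 0.09, and without SEZ control replicate 1 (0.06). Array weights also called both, with medians of -0.15 and 0.12. The medians of the progenitor and astrocyte lists, -0.007 and 0.014, had the opposite sign of their means. Slc1a3, low in cKO replicate 3, was at -1.21 and carried the mean of the astrocyte list, whose other 27 members had an interval from -0.15 to 0.16. Gfap was at -0.20 (SE 0.20) and Egfr at -0.04 (SE 0.13).

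Markers of cortical and septal neurons, which border the dissected tissue, were uneven among the SEZ controls. Slc17a7, a vesicular glutamate transporter of cortical neurons, was at 10.58 and 11.06 in SEZ control replicates 2 and 4, against 8.44 to 8.98 in the other SEZ controls and 7.84 to 8.68 in SEZ cKO samples (difference -1.37, SE 0.45, adjusted p = 1). Tbr1, a transcription factor of cortical projection neurons, was at 8.17 and 8.63 in those controls, against 6.47 to 6.91 and 6.60 to 6.77. The list differed by -0.17 (-0.40 to 0.07, camera adjusted p = 0.0538), and it was called lower without SEZ cKO replicate 1, SEZ control replicate 1 or SEZ control replicate 3, with medians from -0.16 to -0.07. Without SEZ control replicates 2 and 4, a fit chosen after seeing the data, 0 genes passed in SEZ, the medians of the cell cycle and neuroblast lists were -0.26 and -0.15 and both were called. The interferon list was no longer called (adjusted p = 0.0547), with a median of -0.11 against -0.16 over all arrays.

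**Figure D3:**
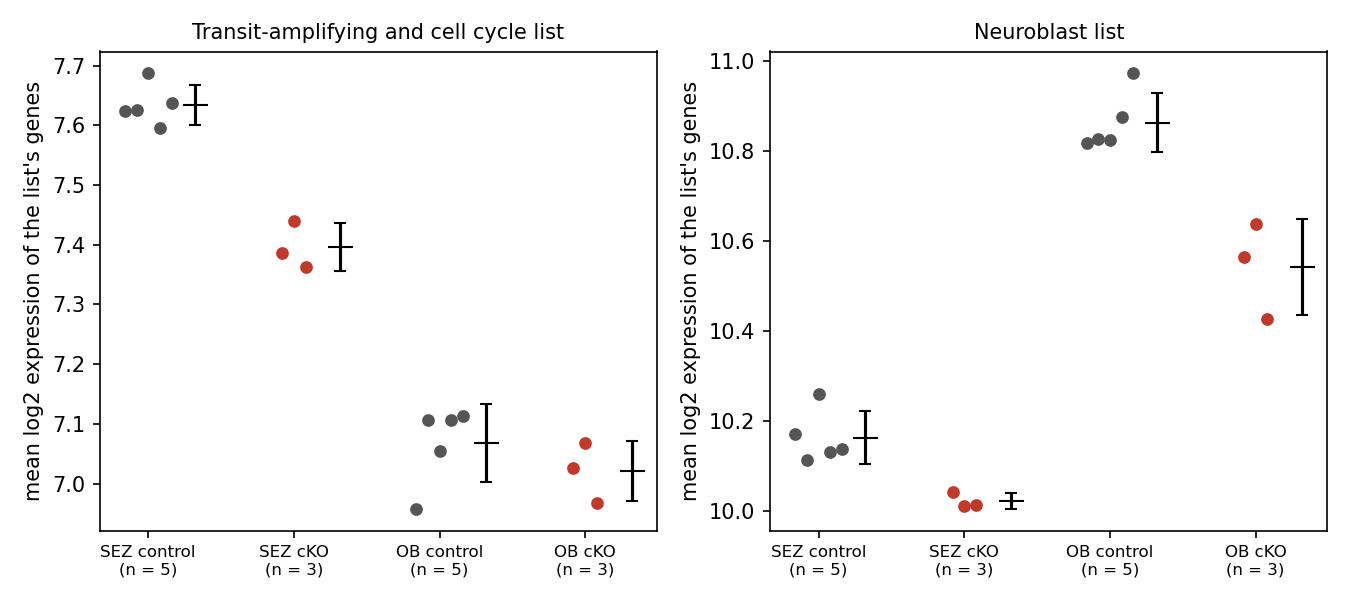
Mean log2 expression of the transit-amplifying and cell cycle list (left) and of the neuroblast list (right) in each sample, by group, with the group's mean and SD beside the points. The 3 SEZ cKO samples lie between 7.36 and 7.44 for the cell cycle list, below the SEZ controls at 7.60 to 7.69, and the 3 OB cKO samples lie between 10.43 and 10.64 for the neuroblast list, below the OB controls at 10.82 to 10.97.

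The cKO effect itself differed between the tissues for 1 gene. Islr2 changed by -1.29 in OB and was at -0.08 in SEZ, a difference of 1.21 (SE 0.15, adjusted p = 0.0117). It did not pass (0 genes) without OB cKO replicate 2, OB cKO replicate 3, SEZ cKO replicate 1 or SEZ cKO replicate 3, and 2 genes passed without SEZ control replicate 3. Without SEZ control replicates 2 and 4 the difference was 1.19 with an adjusted p of 0.117, a similar size with fewer arrays. Ccna2, at -0.73 (SE 0.14, adjusted p = 0.46), did not pass.

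The cell cycle list fell further in SEZ than in OB, by a mean difference of -0.19 (95% interval -0.30 to -0.08, camera adjusted p = 2.88e-14, adjusted p = 0.00508 with an estimated correlation). In OB the same list differed by -0.05 (-0.13 to 0.03) and was not called over all members. It was called lower in OB among genes above the median level (median -0.29, adjusted p = 0.000242) and with cyclic loess (median -0.06, adjusted p = 0.034). The 5 members above that level had a mean difference of -0.26 in OB (-0.40 to -0.13), and Pcna (-0.44) and Mcm7 (-0.33), both of DNA replication, fell when adjusted over the list alone. Among genes above the median level the difference between the tissue effects had a median of 0.02 and was not called. The neuroblast list differed the other way, with 0.18 (0.03 to 0.33, camera adjusted p = 0.00109), a call lost with an estimated correlation (adjusted p = 0.318) and without OB cKO replicate 3. The Wnt pathway list (0.12, -0.01 to 0.24, camera adjusted p = 0.0227) was not called with an estimated correlation (adjusted p = 0.419). That call was also lost without OB cKO replicate 2, OB cKO replicate 3, SEZ cKO replicate 1, SEZ cKO replicate 3, OB control replicate 2 or SEZ control replicate 4, and without SEZ control replicates 2 and 4 (adjusted p = 0.205). The neurogenic network list differed by 0.27 (0.07 to 0.47) and was not called (camera adjusted p = 0.0527, adjusted p = 0.268 with an estimated correlation). It was called in 14 of 34 alternatives, among them those without cKO replicate 1 of either tissue, without OB control replicate 2, 3 or 4 and without SEZ control replicate 2 or 3, with adjusted p over all alternatives from 0.00266 to 0.395.

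As background, the tissues were compared in controls, where 5491 genes differed, 2512 higher and 2979 lower in OB than in SEZ. Genes of olfactory bulb interneurons were much higher in OB. Calb2, calretinin, was 20.3-fold higher (12.68 ± 0.13 against 8.33 ± 0.27, n = 5 each, adjusted p = 1.19e-12). Scgn (secretagogin), Frmd7 and Cpa6 were at 9.98, 11.09 and 11.06 in OB. Their SEZ levels of 5.57, 6.09 and 6.23 lie near the lower quartile of the array values, so no fold is given. Striatal genes were much higher in SEZ, among them Drd2 (-4.96, SE 0.15), Drd1 (-4.47, SE 0.10) and Tac1 (-4.36, SE 0.26), all with adjusted p of 6.72e-10 or below. Scn4b was at 12.62 in SEZ and at 6.54 in OB, also a low level, so no difference is given.

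Of 23 striatal projection neuron markers, 22 were lower in OB than in SEZ, with a mean of -2.70 (95% interval -2.78 to -2.62). Of 24 granule and periglomerular neuron markers 17 were higher in OB and 3 lower (mean 1.25, 95% interval 1.15 to 1.35), and of 16 mitral and tufted cell markers 12 were higher (mean 1.88, 1.68 to 2.07). The neuroblast list was higher in OB (18 of 25, 4 lower, mean 0.70). It also holds genes of young interneurons and shares Meis2 with the granule and periglomerular list, so its mean does not measure neuroblasts alone. Adjusted over the list alone, Ccnd2, Dlx6, Plxna4 and St8sia2 were lower in OB. In SEZ, 23 of 28 cell cycle genes, 27 of 30 ependymal genes and 22 of 23 myelin genes were higher than in OB. Camera called all 7 lists, and an estimated correlation kept all but the myelinating oligodendrocyte list (adjusted p = 0.095). Among genes above the median level the ependymal and cell cycle calls were lost.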

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

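The counts over other splits of the samples were planned before the data were examined, and no test in this part was chosen after its result was seen.

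In OB, the 56 splits of the 8 samples into 3 and 5 ignore the pairing. At least 9 genes came from 2 of them, the real split included. That share is under 0.05 but was not adjusted over the other counts tested here. The other split set cKO replicate 1, control replicate 1 and control replicate 2 apart. It gave 54 genes, more than the real split, so chance is not excluded, and it points to a structure of the samples. Those 3 OB samples were the highest in the meninges and fibroblast list (8.68 to 8.88, against 7.85 to 8.21 in the others). Whether this gave the 54 genes was not tested. The splits that part all 3 same-numbered pairs, as the real one does, are 8, too few for a share under 0.05, with 9 genes in the real split and 0 in the highest other. For the tissue difference in controls, 1 of 100 splits reached 5491 genes and the highest other gave 0. Every other split mixed OB and SEZ arrays in both groups, which puts the tissue difference into the residual spread. Their low counts follow from this, so the splits decide nothing about chance here. Those that part all 5 same-numbered pairs are 14, too few for a share under 0.05, with 5491 genes in the real split and 0 in the highest other.

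In SEZ, 41 of 56 splits had at least the real 492 genes at an unadjusted p under 0.05, and the highest other had 6023. That split set cKO replicate 3, control replicate 1 and control replicate 3 apart, so its count points to a structure of the samples other than the genotype. These are the SEZ samples of one array cluster, which was made from the same values and is not separate evidence. For the difference between tissue effects, 11 of 100 splits gave at least 1 gene, with a highest other of 799, so chance cannot be excluded for Islr2. List counts reached the real value of 3 in 53 of 56 splits for SEZ (highest other 13), in 48 of 56 for OB (highest other 13) and in 88 of 100 for the difference (highest other 15). Chance cannot be excluded for any of these list counts.

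Single samples stood apart from their group in 8 of 151 groups of 5 tested, where chance gives about 1 in 20. Kif11 was 7.8 in SEZ control replicate 1 against 8.1 to 8.19 in the other SEZ controls. SEZ control replicate 3 had Msrb2 at 8.4 against 8.57 to 8.6, Kcnrg at 6.19 against 5.99 to 6.04, and Cpa6 at 6.4 against 6.16 to 6.21. OB control replicate 3 had Olig2 at 9.17 against 8.73 to 8.85 and P2ry12 at 8.33 against 8.24 to 8.26. Gng2 was 10.33 in OB control replicate 1 against 10.15 to 10.2, and Slc1a3 was 12.27 in OB control replicate 2 against 11.64 to 11.72.

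The cKO effect differed between SEZ and OB, by the test of the difference itself, for Islr2 (1.21), and by camera at a preset correlation for 3 gene lists. The median difference, SEZ effect minus OB effect, was 0.06 for the neuroblast list, -0.176 for the transit-amplifying and cell cycle list and 0.061 for the Wnt pathway list. The neuroblast and Wnt calls were lost with an estimated correlation (adjusted p = 0.318 and 0.419) and with fry (adjusted p = 0.395 and 0.614), so for these 2 lists a difference between the tissues rests on the preset correlation. The cell cycle list was not called among genes above the median level. It is dim in OB (7.07 against a median of 8.09 over all genes), and its 5 members above that median differed by -0.261 there. Outside the named genes, 493 of 13767 probe sets with no symbol or several symbols differed between OB and SEZ in controls, and 0 differed by genotype in either tissue (421 in SEZ and 413 in OB at an unadjusted p under 0.05).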

How the results depend on the processing

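Chosen after the results were seen were the within-group component, the array cluster and the fits without both cKO 1 arrays, both cKO 3 arrays or SEZ controls 2 and 4, and the cause of the changes given here was not tested. Of the 2032 alternative values of named genes 1943 stayed, 69 lost and 14 gained a call, 6 moved without a call and 0 reversed. A value without a call stayed if it moved by no more than the within-group SD, whatever its sign. Of 3323 list values 3061 stayed, 50 lost and 174 gained a call, 31 moved and 7 reversed. Among the values that stayed or moved, 70 gene values (at most 0.648 in size) and 303 list values (at most 0.288) changed sign without passing in either setting. Islr2 and Prokr2 passed in OB under all 24 alternatives, while Sfrp2 and Nrep lost their call in 14.

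The 9 OB genes became 3 from OB arrays alone, 5 with cyclic loess, 5 with the replicate block, 28 with the component, 5 without both cKO 1 arrays and 2 without both cKO 3 arrays, and 2 to 9 leaving out 1 array. The SEZ count of 0 became 2 with the replicate block (Ccna2 and Scp2), 4 with the component and 2 with the cluster block, and stayed at 0 leaving out 1 array. The 1 gene with a differing effect became 2 with array weights, 2 with the component, 2 with the cluster block, 0 with neighbouring-tissue covariates, 0 without both cKO 1 arrays 0 without both cKO 3 arrays and 0 without SEZ controls 2 and 4 (0 to 2 leaving out 1 array). The tissue count ranged from 4178 to 7244 (4910 to 5516 leaving out 1 array).

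The 3 SEZ lists became 7 from SEZ arrays alone, 5 with median centring, 6 with array weights, 5 with probe set means, 5 with every probe set, 6 at an adjusted p under 0.1, 1 with an estimated correlation, 1 with fry, 7 without both cKO 1 arrays and 7 without both cKO 3 arrays (2 to 10 leaving out 1 array). The 3 OB lists became 6 among genes above the median level, 5 with cyclic loess (1 higher, 4 lower), 5 with every probe set, 5 with neighbouring-tissue covariates, 5 with the component, 5 without both cKO 1 arrays and 9 without both cKO 3 arrays (4 to 9). The 3 lists with differing effects became 1 among genes above the median level, 6 with array weights, 7 with the replicate block, 9 at an adjusted p under 0.1, 6 with the sex-linked covariate, 1 with an estimated correlation, 1 with fry, 6 with the component, 5 with the cluster block, 6 without both cKO 1 arrays and 5 without SEZ controls 2 and 4 (3 to 8). Camera was not run with the random replicate block.

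Reversed list medians were, for the difference between the tissue effects of the cell cycle list, 0.023 among genes above the median level, and for the OB ependymal list 0.282 there. Without the cKO 1 array of the tissue and without both, the SEZ interferon list was 0.022 and 0.022, and the OB meninges and fibroblast list -0.292 and -0.292 (leaving out 1 array, -0.257 to 0.022 and -0.292 to 0.189). Without both cKO 1 arrays the difference between the tissue effects of the myelinating oligodendrocyte list was -0.143. SEZ cKO and control numbers were not taken as paired (2 of 3 cKO samples correlated best with their own number, as in OB). Few genes of dim lists remain above the median level, and low signal limits them.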

Other observations

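All tests in this part on sample identity, Slc1a3 and the neuroblast list were chosen after the result was seen.

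The SWI/SNF subunit list, the partners of Brg1, differed by -0.01 in SEZ (95% interval -0.07 to 0.05, 28 genes) and by -0.04 in OB (-0.10 to 0.02), with 0 members passing. The polycomb list differed by -0.06 in OB (-0.14 to 0.03), and Ezh2 was its 1 member of 23 that fell. Camera did not call it (adjusted p = 0.235), but called it lower without OB control replicate 2 (median -0.07, adjusted p = 0.042) and over all arrays with the array cluster as a block (median -0.07, adjusted p = 0.0427). The granule and periglomerular neuron list, the mature fate of most adult-born neurons, differed by -0.08 in OB (-0.20 to 0.04), and Prokr2 was its 1 member of 24 that fell. The Notch list differed by 0.02 (-0.06 to 0.10) and the Hedgehog list by less, with an interval from -0.08 to 0.08.

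The SEZ and OB samples of cKO replicate 1 differed in sex-linked genes, with an OB minus SEZ difference of -6.32 for Xist, where the other 7 pairs lay between -1.07 and 0.51. This argues against both samples coming from 1 animal. At 4 further genes whose levels fall into 2 classes (gap of at least 1 on the log2 scale), the pair lay on the same side at 25% of genes and each of the other 7 pairs at 100%. For cKO 2 and controls 2, 4 and 5 a sample of another number also reached 100%, so sharing of sides does not identify an animal. The labels give the control 5 pair different genotypes, since only its SEZ sample lacks a floxed copy. Taken as written, they go against 1 animal for that pair too, although its sides matched. Of these genes, Mir329 was high in exactly the arrays of a single cluster, and only the cKO 1 pair was split between the clusters. A first criterion for an exchange with another SEZ sample, sharing of sides, gave 100% with SEZ cKO replicate 3 but could not separate the samples because OB cKO replicate 1 and OB cKO replicate 3 lay on the same side at all 8 genes, so it was replaced after being seen. With the new criterion 0 of the other pairs were out of place, which argues against an exchange with another SEZ sample. It reads the same sides of the other 7 pairs as given above, so it adds no separate evidence. An exchange among OB samples was not tested. Numbers that do not mark animals, or a sample from outside, may remain as explanations.

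Slc1a3 was 7.6-fold lower in OB cKO replicate 3 and 9.3-fold lower in SEZ cKO replicate 3 than the mean of the other samples of each tissue, differences of -2.93 and -3.22. A loss of astrocytes would lower their other markers too, and the median of the 27 other members of the astrocyte list differed by -0.09 in OB and -0.08 in SEZ (median absolute deviations 0.17 and 0.14). A candidate explanation is that this animal carried the recombinase in both copies of the locus, with the smaller of the differences at -2.93. The labels give no copy number and 1 probe set measured the gene, so it cannot be told apart from another fault at the locus.

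The neuroblast list was lower in OB cKO samples by -0.321. With the array cluster as a block the difference was -0.315 (95% interval -0.428 to -0.202), so the filling of the clusters as cut changed it little. The clusters were cut after each group's mean was removed, so an offset of a whole group along them is not adjusted for. Such an offset is left undecided. Less tissue of the migratory stream in the cKO dissections would lower dividing cells too, and the cell cycle list differed by -0.047 (-0.126 to 0.033). Most of that list is dim in OB, and its 5 members above the median level (Pcna, Mcm7, Mcm4, Mcm5 and Egfr) differed by -0.261 (-0.396 to -0.126), which goes with less stream tissue. That explanation stays open, as does a loss of Brg1 in the lineage, the contrast of the design, since either could lower these genes and the neuroblast genes together.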
